A study of Mus musculus with 5 samples.

How the data were processed

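Chromosome conformation capture with a single viewpoint (4C-seq) was measured in 5 samples of mouse embryonic stem cells, with a bait in the Dppa2/4 domain of chromosome 16. Per the labels' protocols, chromatin was cut with HindIII, ligated, cut again with DpnII and sequenced. The submitters' processing notes name Bowtie2 and the builds mm9 and mm10, and versions are not given in the sources used here. Of the deposited tables used here, the first holds 2 clones of a Cas/129 hybrid line, named A6 and E2 in the labels, each split by the authors into a 129 and a CAST column. The second holds 3 inbred libraries: the unedited line 46C, a 45 kb boundary deletion and a 350 kb boundary deletion, with 1 library each.

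The deposited hybrid values are RPM per allele over 545079 windows of 5 kb in mm10, per the file headers and the values. The deposited inbred values are coverage signal over 19951 windows of 5 kb, without a chromosome column. The last inbred window with reads ended at 98315000, so the inbred table was read as chromosome 16 of mm9. Gene positions came from an annotation of GRCm38.p6, the same build as mm10, and were used for the hybrid clones alone. The baits and builds of the tables differ, so hybrid and inbred values were not compared with each other.

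Both tables held running means over 30 windows, or 150 kb. Differences between neighbouring hybrid values were whole multiples of 1 step, and undoing the running mean gave whole reads for 100% of values, within 0.01, with 0 windows below 0. In the inbred table the windows of each deletion had been set to 0, and leaving them out before undoing the running mean gave 0 windows below 0. Keeping them gave 4343 windows below 0 for the 45 kb deletion and 4730 for the 350 kb deletion. A value in the deposited tables therefore averages its surroundings, so named bins whose own reads go the other way are pointed out.

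Depth was taken from the recovered values. Clone A6 had 1937280 recovered reads in the 129 column and 1311580 in the CAST column, and clone E2 had 2397572 and 1603247. On chromosome 16 these were 466850, 311368, 591918 and 386984 reads. Reads fell in 6.83% and 7.08% of windows for 129 and in 4.51% and 4.62% for CAST. The inbred values corresponded to 1714005 reads for wild type, 1772088 for the 45 kb deletion and 1465714 for the 350 kb deletion. Intervals are 95% Wilson intervals and cover counting error alone, since 4C reads without molecular identifiers are not independent molecules.

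The bait was placed at the centre of the gap without windows, and 50 kb around it was left out. The protocol in the labels names primers that differ from the bait sequences listed for the samples. Without a genome sequence the bait position, on which all distance classes rest, could not be checked against the primers. In the inbred libraries the highest 50-kb bin lay upstream of the gap centre at 48605000 (mm9). In wild type its signal was 8089, at 48350001 to 48400000, against 6349 and 5718 in the bins at the gap edges. For the 45 kb and 350 kb deletions it was 8341 and 8409, at 48400001 to 48450000. The inbred bait position, and with it the nearest distance classes and the upstream to downstream ratios, is therefore uncertain. Upstream means lower coordinates. Shares of the chromosome 16 signal were taken in distance classes with limits at 0.25, 0.5, 1, 2, 5 and 10 Mb on both sides. For the hybrid clones, 50-kb bins up to 5 Mb from the bait were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 2.34), a pseudocount set from the median bin, with clone as a block and Benjamini-Hochberg adjustment at 0.05. Gene values cover the gene and 5 kb on both sides. The limma log2 values are on that scale and understate changes of low bins, while ratios of genes and distance classes have no pseudocount. The test estimated 1 spread for all bins. Gene-rich preference was the log2 ratio of the mean signal in gene-rich to gene-free 500-kb bins over 2 Mb from the bait. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used elsewhere. edgeR 4.0.16 was run on the recovered hybrid reads as an alternative. Another alternative used windows read on both alleles with the running mean undone, with at least 10 reads on each allele summed over the clones, which were 1107 of the 4891 windows of chromosome 16 with reads. This choice also removes windows with the most extreme ratios.

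The bin test was tested on simulated reads for the hybrid allele comparison. With the running mean simulated over 198 bins, limma recovered 19% of 40 bins changed by a log2 of 1 and 74.4% of those changed by 2, with 0.4 and 1.3 false calls per run, and 0 calls per run with no change. Without the running mean, over 193 bins, limma recovered 1.12% and 20%, and edgeR 1.25% and 15.4%. With the running mean, changed bins formed blocks of neighbours, and calls close to a changed bin were not counted as false. Without it, changed bins were scattered, so the simulations differ in more than the running mean. Reads of both alleles were drawn from a shared mean. Windows read on one allele only were therefore not simulated, and the false calls do not cover them.

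Groups, tests, the names of 34 genes and part of the alternatives were fixed before the data were examined. 32 of these genes were found on chromosome 16 of the annotation. Among bins with a mean signal at or above the median, the 5 with the highest and the 5 with the lowest log2 ratio were named, for the hybrid clones where both clones had the same sign. The labels do not say whether the clones came from separate cultures, so the spread between these samples may be technical. The p-values of the main bin test rest on 1 spread shared by all bins. The spread between the clones within a bin therefore does not enter its own p-value. No unedited hybrid library was analysed here, so a difference between alleles holds the strain and the deletions together. The distance profile was planned without a test, since an exact sign-flip test of 2 pairs cannot give a two-sided p below 0.5. A paired t-test, which would rest on 1 residual degree of freedom, was not run. Gene-rich preference of the inbred libraries was left out because no mm9 annotation was used here.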

Results

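4C-seq reads from a bait in the Dppa2/4 domain of chromosome 16 were compared between the alleles of 2 hybrid embryonic stem cell clones, A6 and E2, and between 3 inbred libraries. The hybrid clones carry CRISPR deletions of 3 labelled intervals and have a 129 and a CAST (Mus castaneus) chromosome. The inbred libraries are the wild-type line 46C and deletions of 45 kb and 350 kb at a domain boundary. The series asks about elements in cis that control DNA replication, and 4C measures which parts of the chromosome lie near the bait.

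The first question was whether the labelled deletions were visible, and on which allele. Reads were nearly missing from the 129 allele in intervals 2 and 3. In the second interval (chromosome 16, 48396806 to 48437301, mm10, overlapping one end of Morc1), clone A6 had 26 reads on 129 and 12236 on CAST. Clone E2 had 67 and 18179. The 129 share was 0.212% in A6 (95% Wilson interval 0.145 to 0.311%) and 0.367% in E2 (0.289 to 0.466%). In the third interval (48581359 to 48620367, inside Morc1), A6 had 1 read on 129 and 6766 on CAST, and E2 had 6 and 12501. The first interval (48308399 to 48311882, overlapping Dppa2) lies beside the bait gap. It held 1 read on 129 and 2 on CAST in A6 and 0 on both in E2. With so few reads on CAST as well, these counts do not show whether it was deleted. The deposited running means did not resolve intervals 2 and 3: the log2 ratio of inside to flank differed between alleles by 0.024 ± 0.056 (SD, n = 2) in interval 2 and by -0.14 ± 0.19 in interval 3. In interval 1 it differed by -0.41 ± 0.06, a value from its surroundings, since its own windows held almost no reads.

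The second question was how contacts were spread over distance on each allele. The 129 allele had the higher share from 0.5 to 1 Mb downstream, with 5.55% ± 0.01 of the signal (SD, n = 2) against 2.87% ± 0.14 for CAST, a log2 ratio of 0.95 ± 0.07. This class holds Myh15, a myosin heavy chain gene, and Dzip3, a ubiquitin ligase gene. From 1 to 2 Mb downstream, around Ift57 and Cd47, the ratio was 0.67 ± 0.21. Next to the bait downstream, from 0.05 to 0.25 Mb, which holds the second interval, part of the third and most of Morc1, 129 had 11.2% ± 2.09 and CAST 19.0% ± 0.33, a ratio of -0.77 ± 0.25. With the deleted windows left out of both alleles, this ratio in the recovered reads was -0.55 ± 0.31. Upstream, 129 was higher in the 4 classes up to 2 Mb, with ratios of 0.55 ± 0.18, 0.82 ± 0.04, 0.56 ± 0.12 and 0.37 ± 0.05 from the nearest outward. The ratio of 0.56, at 0.5 to 1 Mb, was 0.27 ± 0.09 over windows read on both alleles. 129 was lower beyond 5 Mb upstream, by -0.46 ± 0.31 at 5 to 10 Mb and -0.45 ± 0.08 over 10 Mb. The first of these was -0.21 ± 0.06 over windows read on both alleles and -0.21 ± 0.63 with the median of windows. From 0.25 to 0.5 Mb downstream the ratio was -0.42 ± 0.17. It was -0.15 ± 0.15 with the running mean undone and 0.23 ± 0.14 over windows read on both alleles. The ratios of 0.24 ± 0.09 at 5 to 10 Mb and 0.25 ± 0.03 over 10 Mb downstream became -0.33 and -0.18 over windows read on both alleles.

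**Figure D1:**
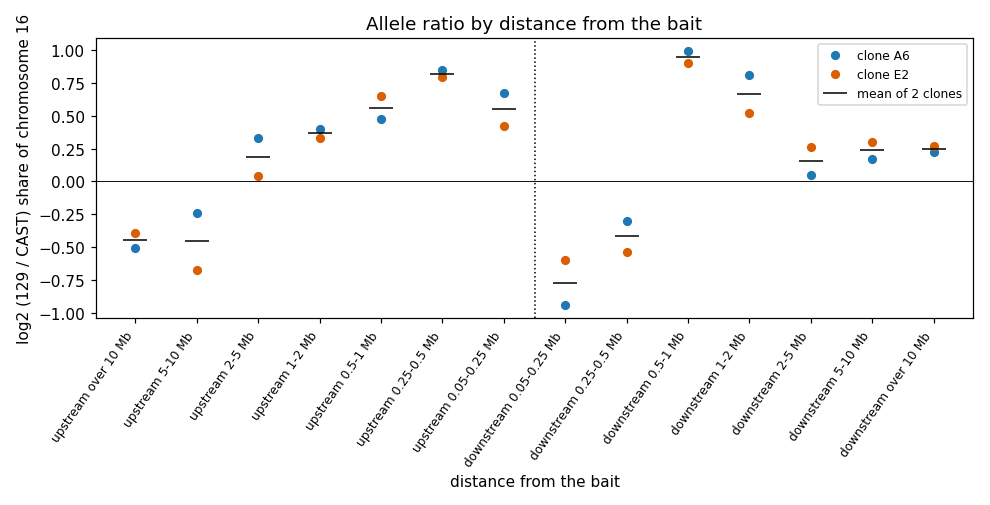
Log2 ratio of the 129 to the CAST share of chromosome 16 signal (y axis) in each distance class from the bait (x axis), with 1 point per clone and a line at the mean of 2 clones. The ratio is 0.95 at 0.5 to 1 Mb downstream and -0.77 at 0.05 to 0.25 Mb downstream.

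The third question was which 50-kb bins differed between the alleles. Myh15 lay in the longest run: from 49.0 to 49.8 Mb, 16 neighbouring bins over Cip2a, Myh15 and Ift57, an intraflagellar transport gene, were higher on 129 by a mean log2 of 1.38, which was 0.79 (mean SE 0.46) over windows read on both alleles. At 49.10 to 49.15 Mb inside Myh15 the RPM was 90.1 ± 11.3 on 129 and 22.5 ± 3.84 on CAST (SD, n = 2; limma log2 1.90, SE 0.34, adjusted p = 4.13e-06). Its own reads were 3000 against 318 in A6 and 4890 against 250 in E2. The bin over the other end of Morc1, a germline transposon-silencing gene, at 48.60 to 48.65 Mb, was lower on 129 (limma log2 -1.28, adjusted p = 0.00198) and overlaps the third interval. Its own reads gave -0.66 in A6 and -0.39 in E2. Its run, from 48.55 to 48.70 Mb, had a mean log2 of -1.02, and of -0.36 (mean SE 0.46) over windows read on both alleles. The bin at 46.40 to 46.45 Mb in Nectin3, a cell adhesion gene, was also lower (limma log2 -0.94, adjusted p = 0.0254). In all, limma placed 75 of 198 bins past the threshold, 55 higher and 20 lower on 129, in 24 runs of neighbouring bins. edgeR on the recovered reads placed 71 of 193 bins past it, and limma and edgeR shared 35 bins, 33 of them in the same direction. More bins of each list were unshared than shared. Lists this long share many bins without any agreement, and the overlap was not tested against that. Neighbouring bins share reads through the running mean and are not independent.

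These calls ended when they rested on windows read on both alleles: limma then placed 0 of 163 bins past the threshold (39 at an unadjusted p under 0.05; edgeR also 0, with 41 unadjusted), and the median log2 over bins went from 0.41 to 0.04. Of the 64 called bins that could be compared, 47 kept their direction, with a median log2 in the called direction of 0.77 (median SE 0.41) against 1.08 (SE 0.34) before. The windows are part of the same reads that gave the calls, so a kept direction is no independent support. The ratios were smaller, the SE larger and the spread was no longer shared by all bins (2.55 prior degrees of freedom), and each of these raises p. Of the 10 bins named by the fixed rule, 7 kept their direction in their own reads in both clones, 2 split the clones and 1 was opposite in both. The opposite bin was the one with the highest named ratio, at 44.85 to 44.90 Mb over Cd200r2. Its running mean gave a limma log2 of 2.14 (adjusted p = 1.8e-07), while its own reads were 23 on 129 and 247 on CAST in A6 and 2 and 155 in E2. The clones split at 50.75 to 50.80 Mb (limma log2 -1.55) and at 44.45 to 44.50 Mb over Cfap44 and Boc (limma log2 -0.997). The other named bins were at 49.05 to 49.10 and 49.15 to 49.20 Mb in Myh15 and at 49.55 to 49.60 Mb, all higher on 129 (limma log2 1.83, 1.71 and 1.72), and at 50.70 to 50.75 Mb, lower (limma log2 -0.96). The own reads of these Myh15 bins gave smaller log2 ratios, 1.04 in A6 and 0.78 in E2, then 0.39 and 0.81. At 49.55 to 49.60 Mb they were larger, at 4.84 and 5.79, but rested on few CAST reads. The reads there were 466 on 129 and 11 on CAST in A6, and 249 and 3 in E2. At 50.70 to 50.75 Mb the own reads gave -1.89 and -2.91.

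**Figure D2:**
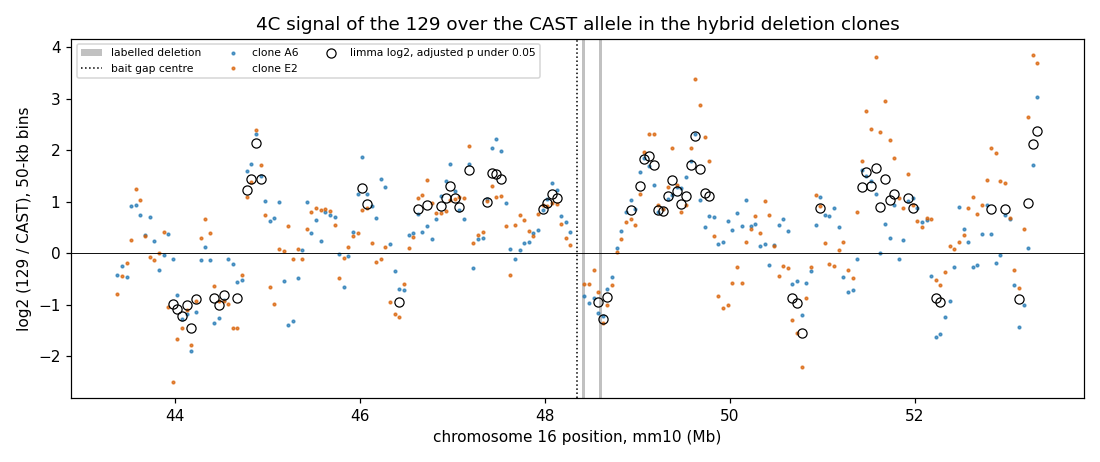
Log2 ratio of 129 to CAST signal (y axis) in 50-kb bins along chromosome 16 in mm10 (x axis, Mb), with a point per clone and circles at the limma estimate of the 75 bins past the threshold. Grey bars are the labelled deletions and the dotted line is the centre of the bait gap; the 16 bins from 49.0 to 49.8 Mb lie above 0.

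Of the 32 genes fixed by name, 17 had the higher mean RPM on 129 in both clones, 11 on CAST in both, and in 4 the clones differed. In the bait domain, 5 of 9 genes were higher on 129 in both clones. The log2 ratio over the gene was 1.87 ± 0.36 (SD, n = 2) for Myh15, 0.68 ± 0.16 for Retnlg, 0.60 ± 0.19 for Retnla and 0.28 ± 0.07 for Retnlb, which are resistin-like genes, and 0.74 ± 0.26 for Dzip3. It was -0.80 ± 0.25 for Morc1, -0.58 ± 0.19 for Dppa2 and -0.06 ± 0.07 for Trat1, and 0.05 ± 0.13 for Dppa4, whose clones differed. Morc1 holds the third labelled interval and part of the second, where 129 reads were nearly missing, so its ratio includes the deletions themselves. Dppa2 and Dppa4 encode chromatin-associated proteins of pluripotent cells. In the reads of the gene itself the ratio was -0.71 for Dzip3, -1.23 for Dppa4 and 3.69 for Retnla. Retnlg held 1993 reads on 129 and 1 on CAST in A6 and 2346 and 3 in E2, so its CAST signal came from its surroundings. Dppa2 held 1 read on 129 and 2 on CAST in A6 and 0 in E2, so its value came from its surroundings. Of the 8 genes with a tested bin at their middle, that bin passed the threshold for Myh15 alone.

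Downstream, Ift57 was at 1.39 ± 1.12 (limma bin log2 1.17, adjusted p = 0.00503), a spread nearly as large as the ratio. Bbx was at 0.54 ± 0.14 and Cblb, a ubiquitin ligase gene, at 0.46 ± 0.18. Cd47, an inhibitory signal to phagocytes, was at -0.31 ± 0.73 with clones that differed, and Alcam was at -0.67 ± 0.62. Upstream, 7 of 8 genes were higher on 129 in both clones. Cd96, a lymphocyte receptor gene, was at 0.97 ± 0.34 (limma bin log2 0.96, adjusted p = 0.0226), Plcxd2 at 0.87 ± 0.62 and Nectin3 at -0.82 ± 0.22. The own reads of Plcxd2 split the clones, with log2 ratios of 1.61 in A6 and -0.32 in E2. Abhd10 and Tagln3 held 0 reads of their own on either allele. Elsewhere on chromosome 16, 6 of 10 genes were higher on CAST in both clones and 2 on 129. Of these 6, Olig1 and Olig2 held 0 reads of their own on either allele, so their values came from their surroundings. Of the 20 genes with the same direction in both clones and at least 10 reads in each column, 17 kept that direction in their own reads. The others were Dzip3, opposite in both clones, and Plcxd2 and Trat1, each opposite in 1 clone. App, the amyloid precursor gene, was at 1.47 ± 0.02 and Gap43, a neuronal growth gene, at -5.50 ± 0.77, with 2 reads on 129 and 157 on CAST in A6 and 9 and 465 in E2.

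The fourth question was whether the alleles differed in contacts with gene-rich parts of chromosome 16 over 2 Mb from the bait. The log2 ratio of the 49 gene-rich to the 61 gene-free bins was -0.13 ± 0.05 on 129 (SD, n = 2) and 0.34 ± 0.03 on CAST. In gene-rich bins the mean RPM was 6.50 on 129 and 7.09 on CAST in A6, and 6.30 and 6.64 in E2. In gene-free bins it was 6.94 and 5.67 in A6, and 7.04 and 5.15 in E2. So 129 was lower in gene-rich bins and higher in gene-free bins. The difference in the log2 ratio was -0.42 in A6 and -0.53 in E2. The same difference over the 18 other autosomes had a mean of -0.09 and an SD of 0.20. By the mean of the clones, chromosome 19 was lower (-0.56), with -0.05 in A6 and -1.07 in E2, and chromosome 10 was close (-0.45), with -0.27 and -0.62. No other autosome was as low as chromosome 16 in both clones.

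**Figure D3:**
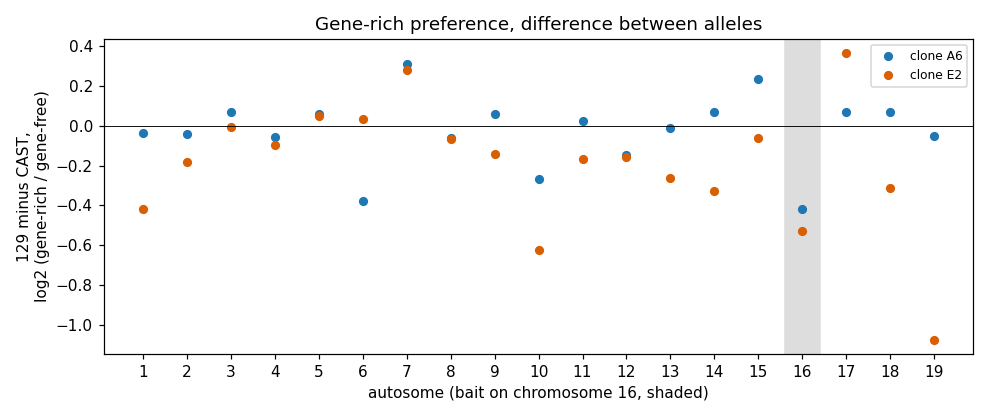
Difference between 129 and CAST in the log2 ratio of gene-rich to gene-free bins (y axis) for each autosome (x axis), with 1 point per clone. Chromosome 16, shaded, is at -0.42 and -0.53.

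The inbred libraries address what loss of a domain boundary does to the contacts of the bait. The deleted windows were at 0 from 48185001 to 48230000 (mm9) in the 45 kb deletion and from 47900001 to 48230000 in the 350 kb deletion, a length of 330 kb. With 1 library per group there is no replicate check, and both deletions share the wild-type library. The bins named and counted here are those with a mean signal at or above the median. Bins with less signal are drawn in the figure and were not counted, and some of them had higher ratios. Outside the deletion, the 350 kb library was higher just upstream of it. The log2 ratio to wild type was 0.79 at 47.85 to 47.90 Mb, 0.63 at 47.80 to 47.85 Mb, and 0.67 and 0.65 in the bins from 47.50 to 47.60 Mb. A bin at 47.40 to 47.45 Mb was at 0.62. It was lower downstream, at -0.72 and -0.83 in the bins from 50.05 to 50.15 Mb and at -0.54 and -0.58 from 49.55 to 49.65 Mb. The bin at 50.15 to 50.20 Mb was at -0.55, but its own reads, 1505 against 1660 in wild type, gave a log2 of 0.086 after scaling for depth. The other 9 of these 10 bins kept their direction in their own reads. The running mean skipped the deleted windows, so beside the deletion it takes in windows from the side of the bait. In own reads the higher bins, from 47.40 Mb upward, were at 0.54, 0.46, 1.00, 0.68 and 0.63.

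In the 45 kb library fewer bins were past 0.5 in either direction, while more of them were below 0: 79 of 98, with a median log2 of -0.17, against 56 of 96 and -0.070 in the 350 kb library. The bins from 47.65 to 47.75 Mb were at -0.55 and -0.49, those from 46.10 to 46.20 Mb at -0.43 and -0.55, and the bin at 49.55 to 49.60 Mb at -0.49. The highest were 0.76 at 44.55 to 44.60 Mb, 0.36 at 44.45 to 44.50 Mb, 0.29 at 48.10 to 48.15 Mb, 0.28 at 47.15 to 47.20 Mb and 0.16 at 48.45 to 48.50 Mb. The own reads of the bin at 44.45 to 44.50 Mb, 1208 against 1389 in wild type, gave -0.25, opposite to its running mean. The other 9 of the 10 bins kept their direction in their own reads, with 0.054 at 48.10 to 48.15 Mb. The running mean of that bin also reaches across the deletion. Of the 98 bins at or above the median signal, 1 was above 0.5 and 2 were below -0.5, against 10 and 6 of 96 bins for the 350 kb deletion. The deleted windows held 1.04% of the wild-type signal for 45 kb and 4.75% for 350 kb. The deposited totals were nearly equal between libraries, so losing these windows raises the other bins, more so in the 350 kb library. The counts and medians of both libraries were not corrected for this.

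**Figure D4:**
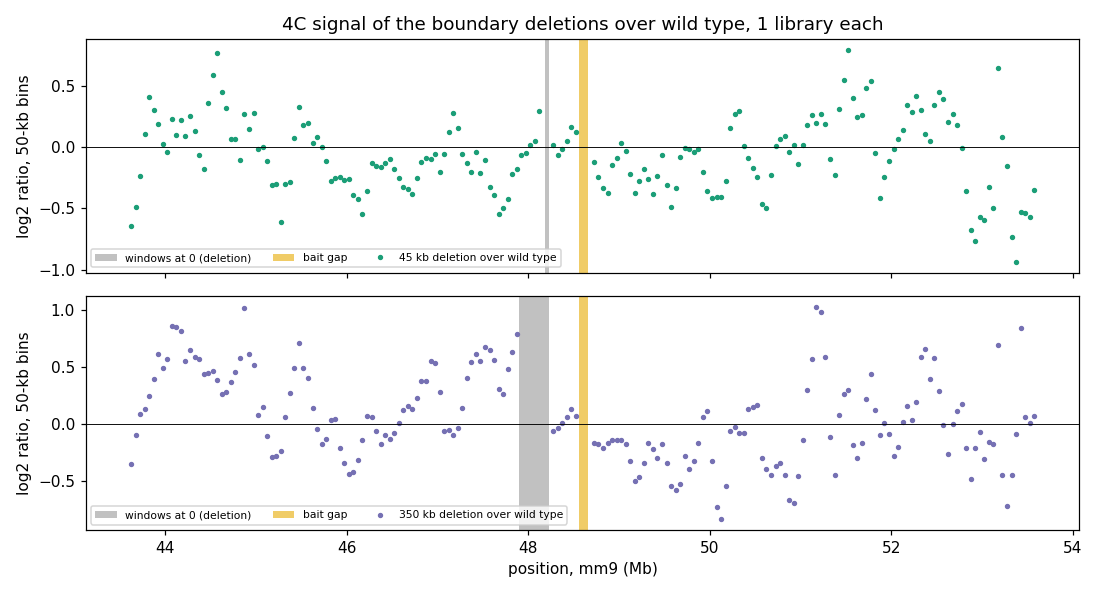
Log2 ratio of each boundary deletion to wild type (y axis) in 50-kb bins by position in mm9 (x axis, Mb), 1 library each, with the deleted windows in grey and the bait gap in yellow. All bins are drawn, including those below the median signal. The 350 kb deletion is at 0.79 beside its upstream edge, where the running mean takes in windows from across the deletion. The own reads of that bin gave 0.63.

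By distance, the 350 kb library held 5.31% of the signal at 1 to 2 Mb upstream against 4.19% in wild type (log2 0.34) and 4.44% against 3.02% at 5 to 10 Mb upstream (log2 0.55). The 45 kb library held 3.77% and 3.11% there (log2 -0.15 and 0.04). At 0.5 to 1 Mb upstream the 350 kb library was at a log2 of -0.50, which includes the deleted windows, and at 0.49 with those windows left out of every library. Downstream at 0.5 to 1 Mb both deletions were lower, with log2 ratios of -0.28 for 45 kb and -0.36 for 350 kb. The log2 ratio of signal upstream to downstream within 1 Mb was 0.76 in wild type, 0.88 in the 45 kb and 0.76 in the 350 kb deletion. With the windows of both deletions left out of every library it was 0.50, 0.66 and 0.76.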

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

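The tests in this part were chosen after the results were seen, apart from the median of windows, a planned setting. The boundary deletions moved in opposite directions against wild type in 3 distance classes, and the difference was not tested, since each is 1 library. The 350 kb minus the 45 kb log2 ratio was 0.49 at 1 to 2 Mb upstream, 0.17 at 2 to 5 Mb upstream and -0.20 at 5 to 10 Mb downstream. With the windows of both deletions left out of every library, the class at 0.5 to 1 Mb upstream also went opposite ways, at -0.35 for 45 kb and 0.49 for 350 kb. The windows left out of this class are deleted in the 350 kb library alone. Over the whole class the 45 kb library was at -0.16. The class at 2 to 5 Mb upstream did not hold: with the median of windows both libraries were higher, at 0.093 and 0.36, and with the deleted windows left out the 350 kb library was at 0.0065. Outside the comparisons, 7.21% of the chromosome X reads of clone A6 (95% Wilson interval 6.95 to 7.47%) and 7.67% of those of clone E2 (7.42 to 7.92%) were in the 129 column. Chromosome X is named here because its reads were used in no comparison. Over all chromosomes the 129 column held more recovered reads than the CAST column. These were 1937280 against 1311580 in A6 and 2397572 against 1603247 in E2. The low 129 share on chromosome X departs from this, and its cause was not tested.

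The higher 129 share at 0.5 to 2 Mb in the hybrid clones, a union of classes chosen after seeing the data, was a log2 ratio of 0.62 ± 0.03 (SD, n = 2). In the recovered reads with the deleted windows left out it was 0.53 ± 0.05, which argues against missing reads there as the whole cause. Over windows read on both alleles it was 0.54 ± 0.12, which argues the same of windows read on one allele. For the called bins the tables leave that open. There 19 of 21 runs kept their direction, but no bin passed the threshold. The median log2 of the called bins went from 1.08 (SE 0.34) to 0.77 (SE 0.41), and the spread was no longer shared by all bins. These windows are part of the same reads that gave the calls, so a kept direction is no independent support. The 19 include runs that fell close to 0, from 1.29 to 0.023 at 51.4 to 51.8 Mb and from 0.98 to 0.036 at 51.9 to 52.0 Mb. Strain and deletion may each contribute, and no unedited hybrid library was analysed here to separate them.

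The lower ratio of gene-rich to gene-free signal on 129 in chromosome 16 was weighed against a strain difference shared by autosomes. Over the 18 other autosomes the median difference was -0.094 (SD 0.20). The -0.47 of chromosome 16 over all windows lay below it by more than that spread. Chromosomes 10 and 19 also lay below it by more than that spread, and chromosomes 7 (0.30) and 17 (0.22) above it by more. The cut therefore does not set chromosome 16 apart, and over all windows a strain difference shared by autosomes was not decided. Counting autosomes, the test made first, also left this open, with 1 as low by the mean and 0 in both clones. Chromosomes 19 (-0.56) and 10 (-0.45) were near chromosome 16, and the other autosomes meet the bait in trans, so a strain difference that varies between chromosomes or acts in cis stays open, as do the deletions. Over windows read on both alleles the difference was -0.25 ± 0.14, against -0.47 over all windows, so windows read on one allele may account for part of it and not for all. That -0.25 lies within the SD of 0.20 of the median of the other autosomes. The other autosomes were not limited to such windows, so there a strain difference of one size also stays open.

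The rise upstream of the 350 kb deletion, from 47.2 to 47.825 Mb, had a median log2 of 0.48 (quartiles 0.30 and 0.63). Over 10 Mb from the bait the median was 0.071, which argues against scaling of the whole library. Higher signal was not confined to this stretch: the library was at 0.55 at 5 to 10 Mb upstream, and at 0.48 with the deleted windows left out. At 2 to 5 Mb upstream it was at 0.077, and at 0.0065 with those windows left out. The explanations weighed here were not tested on those classes. A distance shortened by 330 kb stays open as a candidate explanation: the wild-type decay with distance predicts a rise of 0.50, while against wild-type windows at the shortened distance, which are other sequences, the library was at -0.40 (quartiles -0.63 and -0.11). In the 7 steps of 0.1 Mb just outside, from 46.5 to 47.2 Mb, 5 ratios were below the predicted rise. They differed from it by a median of -0.12. The SD of single steps was 0.22, which does not measure the spread of that median. At 47.1 to 47.2 Mb the ratio was -0.073 against 0.36 predicted. An earlier form of this test, on a stretch picked by eye, argued against the shorter distance, and a changed boundary was not separated from it.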

How the results depend on the processing

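Running means undone, windows read on both alleles, deleted windows left out and edgeR were chosen after seeing the data. The other settings were planned. For the inbred libraries, deleted windows left out means the windows of both deletions, left out of every library. The count of 75 called bins became 151 with 25-kb and 33 with 100-kb bins, which changes how many bins were tested, 25 with edgeR on 100-kb bins, and 0 over windows read on both alleles with limma and with edgeR. Across the 8 other settings it was 59 to 88. Of the 71 bins called by edgeR on reads, 35 were among the 75 of limma, 33 of them in the same direction. More bins of each list were unshared than shared. A count without a clone was not run, since 1 clone leaves no residual spread. The cause was not tested for the changes that follow, apart from those a setting makes by its construction.

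In the hybrid profile (log2, class in Mb in parentheses), windows read on both alleles with the running mean undone gave upstream 0.27 (0.5 to 1), 0.51 (1 to 2) and downstream 0.23 (0.25 to 0.5), 0.66 (0.5 to 1), -0.33 (5 to 10), -0.18 (over 10). The running mean undone with the deleted windows also left out, 2 choices together, gave upstream 0.37 (0.05 to 0.25), 0.61 (0.25 to 0.5), 0.25 (1 to 2) and downstream -0.20 (0.25 to 0.5), 0.82 (0.5 to 1), 0.14 (5 to 10), 0.18 (over 10). The running mean undone alone gave upstream 0.72 (0.25 to 0.5) and downstream -0.15 (0.25 to 0.5), 0.29 (over 10). The median of windows gave upstream 0.88 (0.5 to 1), 0.43 (1 to 2), -0.027 (2 to 5) and downstream 1.41 (0.5 to 1), 0.47 (2 to 5), 0.32 (over 10). The signal as deposited gave upstream 0.86 (0.25 to 0.5) and downstream 0.28 (over 10). Leaving out 20 or 100 kb around the bait moved no class by more than the SD. Leaving out a clone gives the value of the other clone alone, which with 2 clones always lies within the SD and says nothing on stability.

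The gene-rich difference of -0.47 was -0.57 with 1-Mb bins, -0.83 with the median of bins, -0.61 with 5 Mb left out and -0.25 over windows read on both alleles. The allele difference in the labelled intervals was -0.66 and -0.25 in the first, 0.14 and -0.14 in the second, with 50 and 200 kb flanks, and 0.15 in the third with 50 kb flanks. With the running mean undone it was -8.82 in the second and -11.77 in the third. Dzip3 turned to -0.71 in its own reads.

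For the 45 kb deletion, the median of windows gave upstream 0.11 (0.05 to 0.25), -0.070 (0.25 to 0.5), -0.13 (0.5 to 1), -0.11 (1 to 2), 0.093 (2 to 5), -0.0054 (5 to 10), -0.014 (over 10) and downstream -0.24 (0.05 to 0.25), -0.065 (0.25 to 0.5), 0.12 (2 to 5), 0.044 (5 to 10), 0.12 (over 10). Deleted windows left out gave upstream 0.068 (0.05 to 0.25), -0.049 (0.25 to 0.5), -0.35 (0.5 to 1), -0.11 (2 to 5), 0.080 (over 10) and downstream -0.15 (0.05 to 0.25), 0.17 (over 10). The running mean undone gave upstream -0.13 (0.25 to 0.5), -0.19 (0.5 to 1), -0.12 (1 to 2) and downstream -0.16 (0.05 to 0.25), and 100 kb left out gave downstream -0.21 (0.05 to 0.25). For the 350 kb deletion, the median of windows gave upstream 0.097 (0.05 to 0.25), -1.29 (0.25 to 0.5), 0.41 (1 to 2), 0.36 (2 to 5), 0.62 (5 to 10), -0.13 (over 10) and downstream -0.18 (0.05 to 0.25), -0.17 (0.25 to 0.5), -0.28 (0.5 to 1), -0.31 (1 to 2), 0.067 (2 to 5), -0.082 (5 to 10), 0.12 (over 10). Deleted windows left out gave upstream -0.0039 (0.05 to 0.25), -0.12 (0.25 to 0.5), 0.49 (0.5 to 1), 0.27 (1 to 2), 0.0065 (2 to 5), 0.48 (5 to 10), 0.022 (over 10) and downstream -0.21 (0.05 to 0.25), -0.22 (0.25 to 0.5), -0.43 (0.5 to 1), -0.30 (1 to 2), -0.14 (2 to 5), -0.11 (5 to 10), 0.085 (over 10), and 0.070 over 0.5 to 2 Mb on both sides. The running mean undone gave upstream 0.082 (0.05 to 0.25), 0.37 (1 to 2) and downstream -0.18 (0.05 to 0.25), and 100 kb left out gave downstream -0.18 (0.05 to 0.25). The upstream to downstream difference of 0.12 for 45 kb was 0.13 with 100 kb left out and with the running mean undone, 0.11 within 2 Mb and 0.16 without deleted windows. For 350 kb it went from -0.0014 to 0.025 within 500 kb, 0.085 within 2 Mb, 0.029 with the running mean undone and 0.26 without deleted windows. The 2 alleles of a clone were compared as a pair, and without the block for the clone the count was also 75. The inbred groups have 1 library each and no pairs. The inbred gene-rich preference was not run. Few windows held reads, which limits single bins and genes.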

Other observations

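Farther from the bait, the 350 kb library was higher than wild type over a broad upstream stretch. From 33.5 to 43.5 Mb (mm9), 19 of 20 bins of 500 kb were higher, with a median log2 of 0.62, and 14 exceeded 0.5. In the 45 kb library 14 of the 20 were higher, with a median of 0.15. On the downstream side, from 53.5 to 63.5 Mb, 10 of 20 bins were higher in each library. Beyond these stretches, 24 of 60 bins upstream were higher in each library, with a median of -0.23 for 350 kb and -0.055 for 45 kb, and 50 of 69 downstream, with a median of 0.19 in both. The stretch was chosen after seeing the data, and each library is 1 sample. These ratios were not corrected for the signal missing from the deleted windows.

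Some runs of neighbouring bins that passed the threshold between the hybrid alleles, picked after their values were seen, differed in how they held over windows read on both alleles. The bins from 44.75 to 44.95 Mb (mm10) over Cd200r1, Cd200r2, Cd200r3 and Cd200r4 had a mean limma log2 of 1.56, and of -0.76 over windows read on both alleles (mean SE 0.55). The bins from 43.95 to 44.25 Mb, over genes that include Sidt1 and Atp6v1a, had means of -1.10 and -0.79. Of the runs without protein-coding genes, the one from 46.85 to 47.10 Mb had means of 1.06 and 0.89, and the one from 51.4 to 51.8 Mb had 1.29 and 0.023.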
